A study of Saccharomyces cerevisiae with 12 samples.

How the data were processed

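The study measured total RNA from 2 yeast strains, wild type and a gcn5 mutant of the BY4741 background, each without and with Congo Red, on 12 Affymetrix arrays in 4 groups of 3. Per the labels' protocols, an exponentially growing culture was divided, and one part received Congo Red at 30 µg/ml for 3 h while the other grew on without it. The labels describe the samples as biological replicates. Group and number of each array came from its title.

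The deposited values are log2 expression per probe set, made by the authors with GCRMA, per the submitters' processing notes; its version is not given in the sources used here. GCRMA subtracts a background modelled from probe sequence, normalizes the arrays against each other by quantiles and summarizes the probes of a set. Quantile normalization forces similar distributions on all arrays, so a shift of all transcripts in one direction would not be seen, and absent transcripts get a low floor rather than 0. The log2 scale was read from the values, which ran from 2.45 to 14.34 with medians near 9.0 on every array. No detection calls and no probe intensities were used here.

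The table held 5716 probe sets. The platform annotation paired 5498 of them with 1 gene symbol, 0 with several and 218 with none, and 12 symbols were updated through their Entrez identifiers in the RefSeq gene table of assembly R64, which was used only for names and neighbours. All 5498 matched that table. For the 47 genes with several probe sets the one with the highest mean over the 12 arrays was kept, giving 5449 genes, and 5345 genes with log2 over 4 on at least 3 of the 12 arrays were tested. No coordinates are given because no genome build is named for the array. A group below log2 4 on every array was treated as having only a bound, and a fold against it was computed with values under 4 set to 4 and is written as at least that fold.

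Tests used limma 3.58.1 in R 4.3.3: lmFit on 4 group means over all 12 arrays with 8 residual degrees of freedom, contrasts, eBayes, and Benjamini-Hochberg adjustment over the 5345 genes with a threshold of 0.05. The 5 contrasts were Congo Red in wild type, Congo Red in the mutant, the interaction, and mutant against wild type untreated and in Congo Red. Fold thresholds were 2-fold, a log2 change of 1. Values are log2 changes with limma's standard errors, or group means with SD.

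There were 22 gene lists: cell wall integrity response, pathway components, chitin synthesis, glucan synthesis and remodelling, cell wall mannoproteins, general stress, ribosomal proteins, ribosome biogenesis, Gcn4-activated amino acid synthesis, SAGA and ADA subunits, phosphate regulon, mating genes, markers of alpha cells and sporulating diploids, cell separation, G1/S, glucose-repressed carbon use, respiratory chain, glycolysis, ergosterol, unfolded protein response, iron uptake and seripauperins. Some lists share genes, with 7 shared between the integrity response and the mannoproteins and 4 between the response and the glucan list. The integrity response list names genes known from earlier work on cell wall stress. Lists were tested with camera, part of limma, with its preset correlation of 0.01 and adjustment over the 22 lists of a contrast, and again with an estimated correlation and with fry. Members missing from the table, such as NCW2 of the integrity response, were not analysed here. The seripauperins are near-identical copies whose probe sets share signal.

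The lists, contrasts, thresholds, the rule for named genes and all alternatives but 2 were fixed before the data were examined. By that rule the text may name, per comparison, the 10 largest rises and 10 largest falls among passing genes whose groups did not overlap, the 4 members of each list with the smallest p, GCN5 and the marker genes HIS3, LEU2, MET17 and URA3, and for the interaction the 10 largest reductions and 5 largest gains among genes changed at least 2-fold in wild type. The neighbours of GCN5 were named by position. Genes named for the arrays numbered 3, and the short lists of a-specific, alpha-specific, heme-repressed and copper-regulated genes, were chosen after values of these arrays were seen.

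Whether equal numbers pair arrays was checked by the correlation of deviations from the group means. Between the treated and untreated arrays of a strain it was 0.53, 0.74 and 0.67 in wild type and 0.84, 0.57 and 0.79 in the mutant. The labels describe divided cultures, so a second fit used the culture as a block for the Congo Red contrasts and the interaction. The main counts come from the fit without a block. Between the untreated strains it was 0.53, 0.39 and 0.44, so the number was used as a block there. Between the strains in Congo Red it was 0.33, -0.08 and 0.11, so the number pairs those arrays only weakly. It was 0.39, 0.40 and 0.38 between wild type in Congo Red and the untreated mutant. The number was therefore used as a block for the strains in Congo Red as well. That block treats the treated and untreated arrays of a culture as independent, so its spread may be too small for comparing strains. Correlations between arrays were 0.971 to 0.995 within groups and 0.938 to 0.991 between groups, and no columns were identical.

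The tests were run first on simulated data with 200 changed genes among 5345. Without a block, the Congo Red contrast in wild type recovered 34% of changes of 0.5 log2 units, 88% of 1 and 100% of 2, and the interaction recovered 16%, 54% and 98%. With the culture as a block the interaction recovered 38%, 88% and 100%, with 4.12% false among its calls. The block by number was not run on simulated data. Alternatives covered the filter, array centring, quantile and cyclic loess normalization, a floor, the probe set rule, eBayes with trend and robust settings, array weights, fits of only the groups compared, blocks and leaving out each array in turn.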

Results

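Gene expression was measured in budding yeast, Saccharomyces cerevisiae, of the BY4741 background with Affymetrix expression arrays. The wild type was set beside a mutant of GCN5, which encodes the histone acetyltransferase of the SAGA and ADA coactivator complexes. Each strain was grown without and with Congo Red, a dye that binds chitin and glucans and disturbs assembly of the cell wall. Congo Red was given at 30 µg/ml for 3 h to one part of a divided culture, and the other part was left untreated. There were 3 biological samples for each of the 4 groups, 12 arrays in all, and the number of arrays limits the precision. The arrays had similar distributions, with medians between 8.98 and 9.05 on the log2 scale. After a filter on dim genes, 5345 genes were compared.

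GCN5 (YGR252W) itself was read first because it checks the labels. Its log2 level was 8.26 ± 0.11 (SD, n = 3) in untreated wild type and 8.25 ± 0.05 (SD, n = 3) in wild type with Congo Red. In the mutant it was 3.72 ± 0.36 (SD, n = 3) untreated and 3.39 ± 0.33 (SD, n = 3) with Congo Red, near the signal of absent transcripts. All 6 mutant arrays lay below all 6 wild type arrays, with the highest mutant array at 4.08 and the lowest wild type array at 8.13. With signals under log2 4 set to 4, GCN5 was at least 18.8-fold lower in the untreated mutant (adjusted p = 3.5e-07) and at least 19-fold lower in the mutant with Congo Red (adjusted p = 1.7e-07). The auxotrophic markers of the background, URA3 and MET17, stayed below log2 4 on all 12 arrays, and LEU2 lay between 3.93 and 5.29. HIS3 was read between 9.24 and 10.08, but this background carries only a partial deletion of the gene, so its probe set checks nothing. Of the genes next to GCN5 on its chromosome, MGA1, NOP19, PUP2, ENO1 and COQ6, none passed the threshold between the untreated strains, with adjusted p from 0.121 to 0.867.

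The first comparison asked which genes respond to Congo Red in wild type cells. Genes of the cell wall stress response were among the largest rises. PIR3, a wall protein attached to glucan, rose by 5.16 ± 0.54 on the log2 scale (SE, n = 3 arrays per group; 35.8-fold, adjusted p = 1.9e-04), and KDX1, a relative of the MAP kinase Slt2, rose by 4.19 ± 0.22 (SE; 18.3-fold, adjusted p = 1.3e-06). CRG1, which encodes a methyltransferase, was 10.8-fold higher, YPL088W, a putative aryl alcohol dehydrogenase gene, 7.59-fold, SRL3 7.46-fold and YPS3, a wall-anchored aspartic protease gene, 6.41-fold. GSC2, which encodes the stress-inducible subunit of glucan synthase and is also called FKS2, was 6.16-fold higher, from 9.34 ± 0.18 to 11.96 ± 0.17 (SD, n = 3 each; adjusted p = 0.00424). BAG7, encoding a GTPase activating protein for Rho1, rose by 2.56 ± 0.12 (SE; adjusted p = 4.8e-07), at least 5.62-fold with its dim values set to the floor. YNR065C rose 5.12-fold and PRM10 4.72-fold.

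Of the list of genes known to respond through the Slt2 and Rlm1 branch of the cell wall integrity pathway, 18 of the 20 measured rose, 0 fell and 2 did not pass, with a median log2 change of 1.35. The plasma membrane protein gene PUN1 rose by 1.75 ± 0.12 and PTP2, a phosphatase of MAP kinases, by 1.41 ± 0.11 (SE). Among the components of the pathway 7 of 27 rose, 0 fell and 20 did not pass. These included the MAP kinase gene SLT2, up by 1.89 ± 0.15, and the gene of its transcription factor, RLM1, up by 1.22 ± 0.12 (SE). The first list stood apart from other genes (camera, adjusted p = 4.1e-29, and adjusted p = 0.00595 with an estimated correlation), and the component list did so with the preset correlation (adjusted p = 1.5e-04) but not with an estimated one (adjusted p = 0.0935). Adjusted over the list alone, 20 of the 20 response genes and 8 of the 27 components were higher.

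Chitin synthesis genes rose in 7 of 14 cases, 0 fell and 7 did not pass (adjusted p = 1.7e-07, and adjusted p = 0.0182 with an estimated correlation). GFA1 and PCM1, enzymes on the path to the chitin precursor UDP-N-acetylglucosamine, rose by 1.42 ± 0.13 and 1.17 ± 0.12, and the chitin synthase gene CHS1 by 1.27 ± 0.13 (SE). Of 24 genes of glucan synthesis and remodelling 10 rose, 0 fell and 14 did not pass, with the exoglucanase gene EXG2 up by 1.15 ± 0.13 and the transglycosylase gene CRH1 up by 1.30 ± 0.20 (SE). That list had an adjusted p = 8.1e-06 with the preset correlation and an adjusted p = 0.0935 with an estimated correlation. Of 26 cell wall mannoprotein genes 8 rose, 1 fell and 17 did not pass (adjusted p = 1.5e-04, and adjusted p = 0.0182 with an estimated correlation). PST1 rose by 1.85 ± 0.16 and HSP150 by 0.64 ± 0.08 (SE).

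Genes of ribosome production fell in wild type. Of 55 ribosome biogenesis genes 0 rose, 31 fell and 24 did not pass, with a median log2 change of -0.47 (adjusted p = 1.7e-25, but adjusted p = 0.0563 with an estimated correlation). RRP8, an rRNA methyltransferase gene, fell by 0.81 ± 0.11 and BRX1, needed for the large subunit, by 0.59 ± 0.08 (SE). Among the largest falls outside the list were FAF1 and SDA1, which also act in ribosome assembly, at -1.04 ± 0.25 and -0.89 ± 0.11 (SE). The vacuolar aminopeptidase gene APE1 fell 3.17-fold, SHU2, a recombination repair gene, 2.77-fold, GUP2 2.34-fold and the oligopeptide transporter gene OPT1 2.27-fold. YBL100W-A fell 4.57-fold, but it belongs to a Ty retrotransposon with near-identical copies, so its probe set reads several elements. Of 127 ribosomal protein genes 0 rose and 1 fell, RPL27B at -0.28 ± 0.08 (SE), a call lost when each array was centred on its median (adjusted p = 0.0576). The median of that list was -0.06 (adjusted p = 0.0025, and adjusted p = 0.576 with an estimated correlation).

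Of 20 genes of the unfolded protein response 3 rose and 17 did not pass, YET3 by 0.78 ± 0.09, SIL1 by 0.61 ± 0.13 and the disulfide isomerase gene PDI1 by 0.34 ± 0.08 (SE; list adjusted p = 1.8e-04, and adjusted p = 0.0935 with an estimated correlation). Of 36 general stress genes 4 rose and 32 did not pass, among them the trehalase gene NTH1 by 1.06 ± 0.19 and HSP12 by 1.31 ± 0.34 (SE; list adjusted p = 1.5e-05, and adjusted p = 0.576 with an estimated correlation). Of 16 measured markers of alpha cells and sporulating diploids 2 rose, the meiotic genes IME2 by 0.71 ± 0.19 and SPO11 by 1.42 ± 0.38 (SE; list adjusted p = 0.0358, and adjusted p = 0.518 with an estimated correlation). In the glucose-repressed list 1 of 30 rose, IDP2 by 0.52 ± 0.13 (SE; list adjusted p = 0.0311), in the Gcn4 list of amino acid synthesis 1 of 49 fell, the lysine pathway gene LYS20 by 0.86 ± 0.22 (SE; list adjusted p = 0.0439), and of 12 seripauperin genes 0 passed (list adjusted p = 0.0419). Each of these last 3 lists had an adjusted p = 0.576 with an estimated correlation. In the G1/S list HO fell by 0.85 ± 0.17 and SVS1 rose by 0.68 ± 0.15 (SE), and 19 of 21 did not pass. Without a block, no member passed among 16 phosphate genes, 23 mating genes, 15 cell separation genes, 37 respiratory chain genes, 15 glycolysis genes, 26 ergosterol genes, 20 iron uptake genes and 20 SAGA and ADA subunits.

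In all, 494 of the 5345 genes passed in wild type, 285 higher and 209 lower, and 91 of them changed at least 2-fold, 85 higher and 6 lower (limma). With the culture as a block 1272 genes passed, 658 higher and 614 lower, including all 494, and the phosphate list (adjusted p = 0.0237, lower) and the respiratory chain list (adjusted p = 0.00426, higher) passed as well. Both had an adjusted p = 0.903 with an estimated correlation and no block. With the block the members passing, higher and lower, were 16 and 0 of the general stress genes, 9 and 0 of the unfolded protein response, and 12 and 2 of the pathway components. They were 0 and 50 of ribosome biogenesis, 0 and 15 of the Gcn4 targets, 10 and 1 of the respiratory chain, 5 and 0 of the glucose-repressed genes and 5 and 0 of the seripauperins. They were 1 and 3 of the phosphate genes, 2 and 4 of iron uptake, 2 and 2 of cell separation, and 3 and 3 of the G1/S genes. They were 1 and 1 of the mating genes, 0 and 3 of the ribosomal proteins and 1 and 0 of the ergosterol genes. They were 20 and 0 of the integrity response genes, 8 and 0 of the chitin genes, 14 and 1 of the glucan genes, 11 and 2 of the mannoproteins and 3 and 0 of the diploid markers. The count was 260 without the untreated array numbered 3 and 328 without the Congo Red array numbered 2. Without single arrays, some of the calls above were lost, with the highest adjusted p as follows: RPL27B 0.18, SPO11 0.149, IME2 0.138, IDP2 0.131, HSP12 0.125 and LYS20 0.12. The same held for FAF1 0.105, PDI1 0.0807, YBL100W-A 0.07, SVS1 0.0645, SIL1 0.0641 and OPT1 0.0639. Among the lists it held for the seripauperins 0.415, Gcn4 targets 0.408, glucose-repressed genes 0.273, ribosomal proteins 0.121 and diploid markers 0.12.

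**Figure D1:**
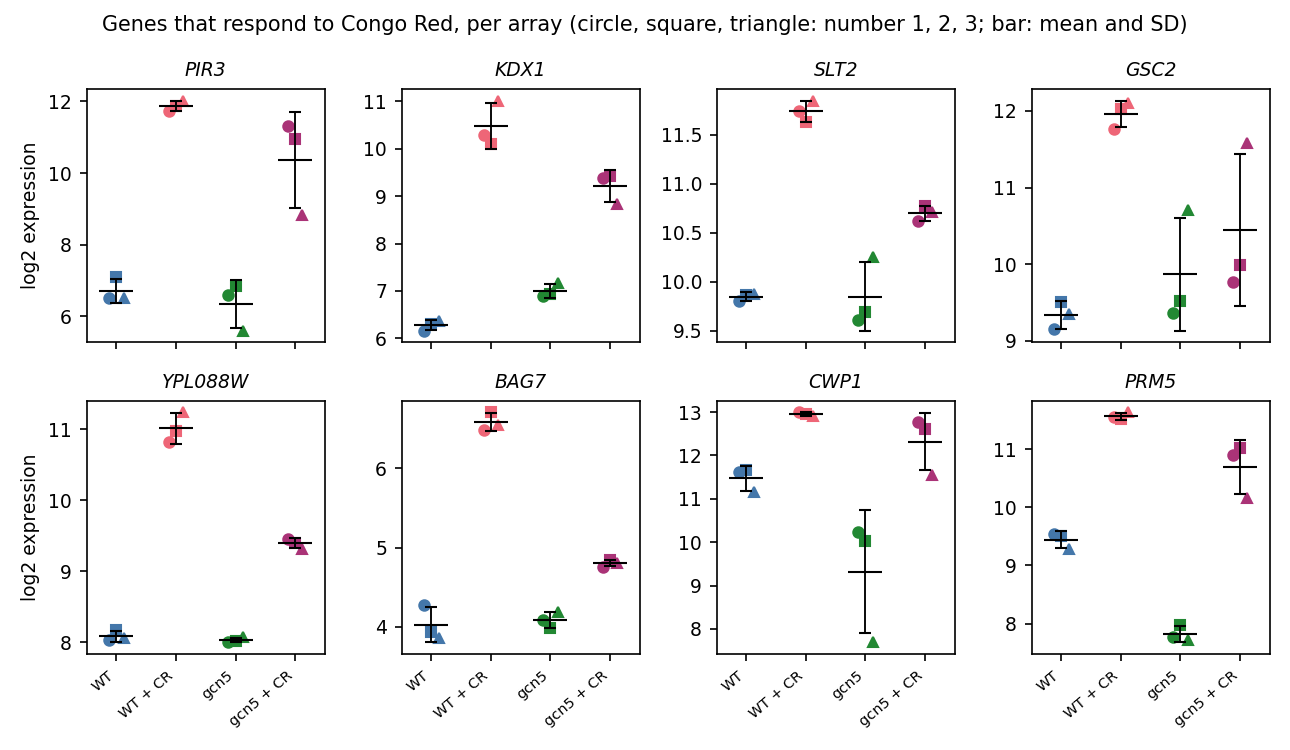
Log2 expression of YPL088W and 7 genes of the cell wall integrity lists on each of the 12 arrays, with circles, squares and triangles for the arrays numbered 1, 2 and 3 of a group and horizontal lines with bars for the mean and SD (n = 3). PIR3 went from 6.71 to 11.87 in wild type and from 6.35 to 10.37 in the mutant, and YPL088W from 8.09 to 11.01 and from 8.03 to 9.39.

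The second comparison asked which genes respond to Congo Red in the gcn5 mutant. Genes of the wall were again among the largest rises. PIR3 rose by 4.02 ± 0.54 (SE, n = 3 arrays per group; 16.2-fold, adjusted p = 0.00558), the mannoprotein gene CWP1 by 3.00 ± 0.56 (SE; 7.99-fold, adjusted p = 0.0266) and PRM5, a cell integrity target, by 2.88 ± 0.19 (SE; 7.35-fold, adjusted p = 2.6e-05). SRL3 was 6.72-fold higher, KDX1 4.65-fold, YPS3 4.44-fold, CRG1 4.02-fold and AFR1, a gene of the mating projection, 3.85-fold. PRM10 was 2.58-fold and YPL088W 2.57-fold higher.

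Of the 20 cell wall integrity response genes 12 rose, 0 fell and 8 did not pass, with a median of 0.82, and 19 were higher adjusted over the list alone (list adjusted p = 2.9e-45, and adjusted p = 0.00123 with an estimated correlation). Of the 27 pathway components 4 rose: PTP2 by 0.93 ± 0.11, SLT2 by 0.85 ± 0.15, BAG7 by 0.71 ± 0.12 and RLM1 by 0.60 ± 0.12 (SE; list adjusted p = 3.9e-05, and adjusted p = 0.0889 with an estimated correlation). Of 14 chitin genes 4 rose, among them GFA1 by 0.98 ± 0.13 and CHS1 by 0.94 ± 0.13 (SE; list adjusted p = 3.2e-09, and adjusted p = 0.0136 with an estimated correlation). Of 26 mannoprotein genes 5 rose, with PST1 up by 1.31 ± 0.16 (SE), but the list's median was 0.00 beside a mean of 0.41 (adjusted p = 5.2e-04, and adjusted p = 0.0204 with an estimated correlation). Of 24 glucan genes 1 rose, the exoglucanase gene EXG1 by 0.49 ± 0.09 (SE; list adjusted p = 6.6e-07, and adjusted p = 0.0767 with an estimated correlation).

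No ribosome biogenesis gene of 55 passed in the mutant, and the list's median was -0.17 (adjusted p = 3.2e-09, but adjusted p = 0.31 with an estimated correlation). The unfolded protein response list, with 0 of 20 passing, had a median of 0.08 (adjusted p = 0.0146, and adjusted p = 0.31 with an estimated correlation). The ribosomal protein list (adjusted p = 0.00172, median -0.06) and the respiratory chain list (adjusted p = 0.0146, median 0.14) had 0 members passing, and adjusted p = 0.758 and adjusted p = 0.896 with an estimated correlation. The respiratory chain call turned to the other direction without the untreated array numbered 3 (adjusted p = 0.15) and was lost without the Congo Red arrays numbered 1 and 2 (adjusted p = 0.678 and 0.758). The falls were small and few: FMP48 at -0.73 ± 0.15, CIN5, a stress transcription factor gene, at -0.66 ± 0.12, ATO3 at -0.49 ± 0.10 and YMR209C at -0.39 ± 0.08 (SE). None of these 4 falls passed without both mutant arrays numbered 3, with adjusted p from 0.0503 to 0.192. IME2 of the diploid markers rose by 0.91 ± 0.19 and SVS1 of the G1/S list by 0.83 ± 0.15 (SE), both calls also lost without those arrays, at adjusted p = 0.225 and adjusted p = 0.072. Without those arrays the calls of RLM1 (adjusted p = 0.072), BAG7 (adjusted p = 0.0518), EXG1 (adjusted p = 0.0528) and the ribosomal protein list (adjusted p = 0.54) were lost as well. Without a block, no general stress, glucose-repressed, Gcn4, phosphate, mating, cell separation, glycolysis, ergosterol, iron uptake, seripauperin or SAGA and ADA subunit gene passed.

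In the mutant 62 genes passed, 58 higher and 4 lower, and 17 of them were at least 2-fold higher and 0 at least 2-fold lower. With the culture as a block 212 passed, 150 higher and 62 lower, including all 62, and the Gcn4 list (adjusted p = 0.0343, lower), the iron uptake list (adjusted p = 4.3e-05, lower) and the seripauperins (adjusted p = 0.0111, higher) passed as well. These had adjusted p = 0.758, adjusted p = 0.949 and adjusted p = 0.758 with an estimated correlation and no block. With the block the members passing, higher and lower, were 18 and 0 of the integrity response genes, 6 and 0 of the pathway components, 7 and 0 of the chitin genes, 6 and 0 of the glucan genes, and 8 and 3 of the mannoproteins. They were 2 and 0 of the respiratory chain, 0 and 3 of iron uptake and 1 and 1 of general stress, and 0 and 1 each of ribosome biogenesis, Gcn4 targets, phosphate and mating genes. The count was 22, 17 and 38 without the untreated arrays numbered 1, 2 and 3, 19 and 24 without the Congo Red arrays numbered 1 and 2, and 15 when only these 6 arrays were fitted, and the count at 2-fold was 11 without the untreated array numbered 2 and 11 without the Congo Red array numbered 1. Without single arrays, some of the calls above were lost, with the highest adjusted p as follows: IME2 0.223, RLM1 0.207, ATO3 0.204, YMR209C 0.196, FMP48 0.184, and CIN5 0.152. The same held for CWP1 0.132, SLT2 0.109, EXG1 0.1, SVS1 0.0945, AFR1 0.0831 and BAG7 0.0831, and among the lists for ribosomal proteins 0.649 and the unfolded protein response 0.147.

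The third comparison asked whether the Congo Red effect differs between the strains, by the interaction of strain and treatment. The rise of BAG7 was smaller in the mutant, with a difference of -1.85 ± 0.17 log2 units (SE, n = 3 arrays per group; adjusted p = 0.00129). BAG7 was near the floor in both untreated strains, at 4.02 and 4.09, so the size of that difference rests on 6.58 against 4.80 in Congo Red, and it was -1.78 with values under log2 4 set to 4 (adjusted p = 4.7e-04). The rise of YPL088W was smaller in the mutant by 1.56 ± 0.15 (SE; adjusted p = 0.0013) and that of HAL1, a salt tolerance gene, by 1.46 ± 0.17 (SE; adjusted p = 0.00765). YPL088W went from 8.09 ± 0.07 to 11.01 ± 0.21 in wild type and from 8.03 ± 0.03 to 9.39 ± 0.07 in the mutant (SD, n = 3 each). HAL1 went from 6.93 ± 0.21 to 9.03 ± 0.08 and from 6.94 ± 0.15 to 7.58 ± 0.12 (SD, n = 3 each). These were the only 3 genes to pass over all 5345 in this fit, and 310 had an unadjusted p under 0.05. All 3 passed without any single array, the count was 5 without the wild type Congo Red array numbered 3, and the HAL1 call was lost without both mutant arrays numbered 3 (adjusted p = 0.0564).

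With the culture as a block 30 genes passed, 26 with a lower and 4 with a higher Congo Red effect in the mutant. Lower and higher refer to the signed log2 change, so a smaller fall counts as higher. GSC2 then differed by -2.04 ± 0.14 (SE; adjusted p = 0.00149, against adjusted p = 0.556 without the block), KDX1 by -1.98 ± 0.27 (SE; adjusted p = 0.0234, against 0.0588 without the block) and SLT2 by -1.04 ± 0.17 (SE; adjusted p = 0.0413, against 0.2 without the block). CRG1 (adjusted p = 0.0192), SPI1 (adjusted p = 0.00967), AFB1 (adjusted p = 0.0138) and EXG2 (adjusted p = 0.0413) also had a lower Congo Red effect in the mutant in that fit. APE1 fell less in the mutant, with a difference of 1.38 ± 0.21 (SE; adjusted p = 0.0285 with the block, against 0.557 without it). It went from 10.39 to 8.73 in wild type and from 10.71 to 10.43 in the mutant. With the block, 3 members of the integrity response list and 2 each of the pathway components, glucan and mannoprotein lists had a lower effect in the mutant. PRM5 had a larger change in the mutant by 0.75 ± 0.27 (SE), which did not pass in either fit (adjusted p = 0.692, and 0.128 with the block).

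The 85 genes at least 2-fold higher in wild type were followed as a set. Their median log2 change was 1.30 in wild type and 0.65 in the mutant, and 83 of the 85 had a smaller change in the mutant. Of the 85, 35 passed in the mutant and 16 did so with at least a 2-fold rise, while 55 passed adjusted over the list alone and 55 with the culture as a block. The interaction passed for 3 of the 85 over all genes, for 55 adjusted over the list alone and for 22 over all genes with the block. This list was chosen on these arrays, so the counts over it alone are not independent evidence of the direction. The median ratio of the mutant change to the wild type change was 0.493, with quartiles of 0.279 and 0.599. In 100 simulations with equal effects in both strains, choosing genes on wild type gave median ratios between 0.866 and 0.991. There a median of 66% and at most 82.8% of the chosen genes had a smaller change in the mutant, against 97.6% here. The simulated noise was independent between genes and arrays, and a median of 49 genes was chosen. In the other direction, 16 of the 17 genes at least 2-fold higher in the mutant passed in wild type, and 14 of the 17 had the larger change in wild type. Of the 6 genes at least 2-fold lower in wild type, 0 passed in the mutant and 6 had a smaller change there. The count of 35 was 17, 15, 16 and 17 without the untreated mutant arrays numbered 1 and 2 and the Congo Red mutant arrays numbered 1 and 2.

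Across all genes the Congo Red effects in the strains correlated with Pearson's r = 0.71 and Spearman's rho = 0.54, where genes are not independent replicates. There were 56 genes higher in both strains, against 3.09 for independent lists, and 3 lower in both, against 0.156. Of the gene lists, cell wall integrity response (adjusted p = 1.2e-07), its pathway components (adjusted p = 0.0055), chitin synthesis (adjusted p = 0.00266), mannoproteins (adjusted p = 0.0205), general stress (adjusted p = 6.5e-05), unfolded protein response (adjusted p = 0.0147) and glucose-repressed genes (adjusted p = 0.0205) had a lower Congo Red effect in the mutant by camera. Ribosome biogenesis fell less in the mutant (adjusted p = 2.8e-20), with a median difference of 0.27 and 54 of 55 genes above 0. With an estimated correlation 0 of the 22 lists passed, and these 8 had adjusted p of 0.127, 0.254, 0.147, 0.127, 0.569, 0.275, 0.569 and 0.127 in the order given. Without single arrays the calls of glucose-repressed genes, general stress, unfolded protein response and mannoproteins were lost, with adjusted p up to 0.316, 0.26, 0.105 and 0.0718, and 14 lists passed without the mutant Congo Red array numbered 3. The unfolded protein response call was also lost without both mutant arrays numbered 3 (adjusted p = 0.147). With the culture as a block the glucan list (adjusted p = 0.0338, lower), the phosphate list (adjusted p = 0.0273, higher) and the G1/S list (adjusted p = 0.0339, higher) passed as well. These had adjusted p = 0.526, adjusted p = 0.889 and adjusted p = 0.253 with an estimated correlation and no block.

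**Figure D2:**
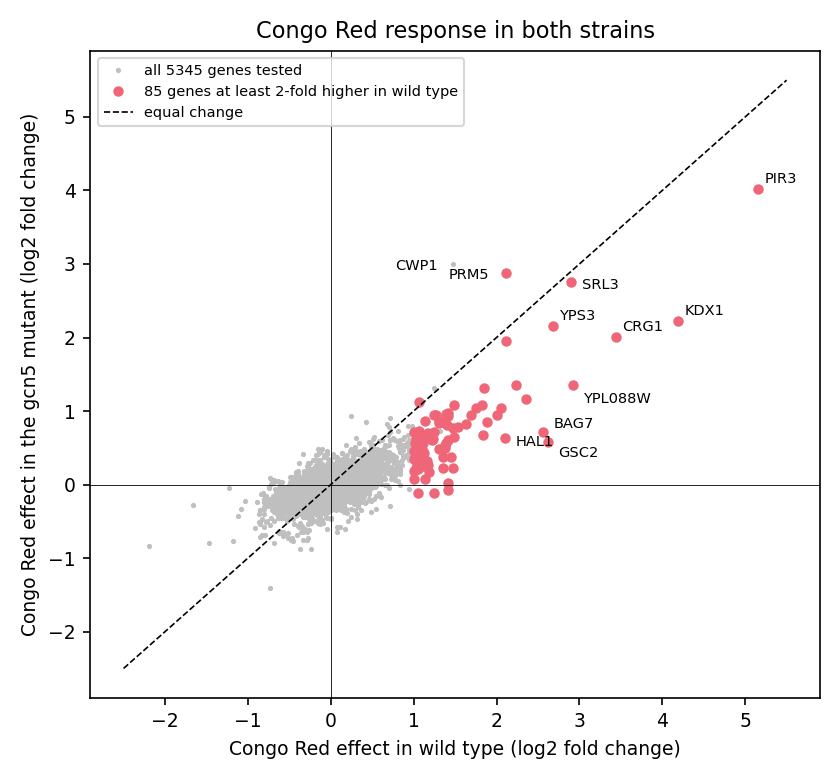
Log2 fold change with Congo Red in wild type (horizontal axis) and in the gcn5 mutant (vertical axis) for the 5345 genes tested, with the 85 genes at least 2-fold higher in wild type in colour and a dashed line where the changes are equal. Of the 85 genes 83 lie below the line, and PRM5 lies above it.

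**Figure D3:**
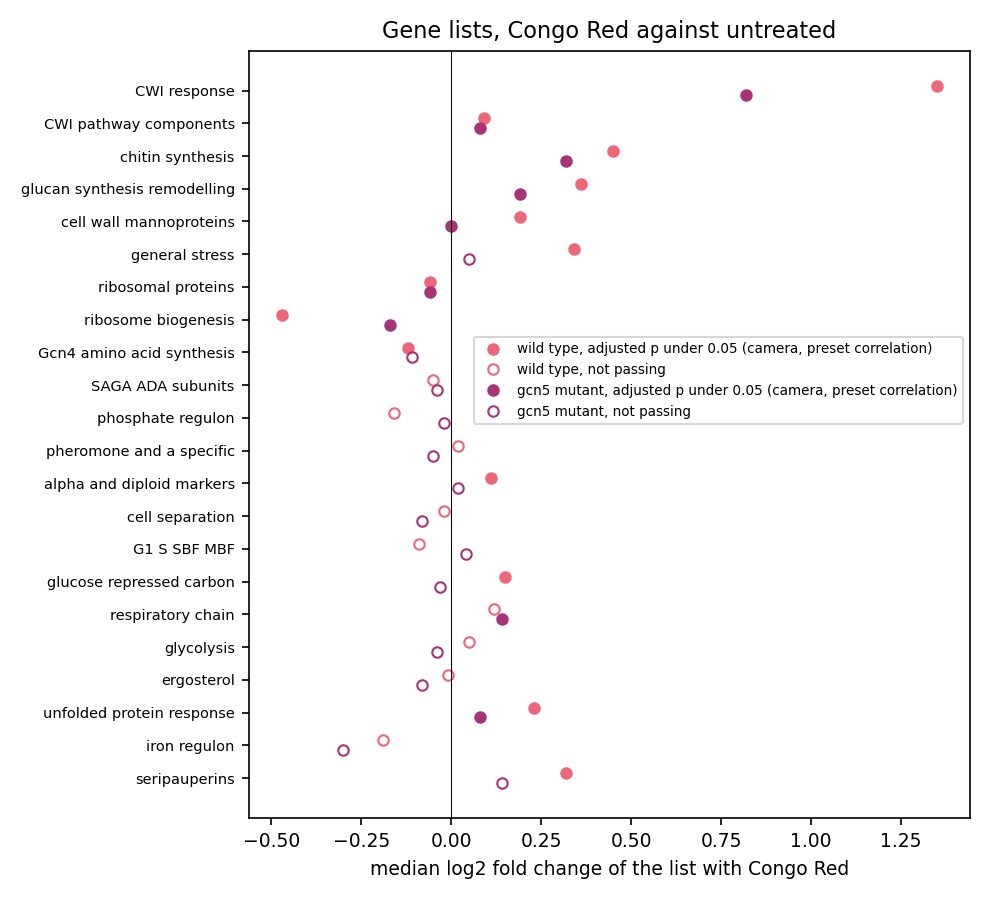
Median log2 fold change with Congo Red of each of the 22 gene lists in wild type and in the gcn5 mutant, with filled points where camera with its preset correlation gave an adjusted p under 0.05. The cell wall integrity response lies at 1.35 in wild type and 0.82 in the mutant, and ribosome biogenesis at -0.47 and -0.17.

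The fourth comparison asked how the mutant differs from wild type without Congo Red. Genes of phosphate uptake and of mating were among those lower in the mutant. PHO84, the high-affinity phosphate transporter gene, changed by -6.52 ± 1.19 on the log2 scale (SE, n = 3 arrays per group; 91.6-fold, adjusted p = 0.00722), PHO11, a secreted acid phosphatase gene, was 17.1-fold lower and SPL2, a regulator of phosphate transport, 15.6-fold lower. MFA1, a gene of the mating pheromone a-factor, was 12.2-fold lower (adjusted p = 8.7e-04) and FUS1, which acts in cell fusion, 8.14-fold lower (adjusted p = 0.0117). ARG1 and ARG3, enzymes of arginine synthesis, were higher by 3.61 ± 0.45 and 3.60 ± 0.36 (SE; 12.2-fold and 12.1-fold, adjusted p = 9.3e-04 and 2.2e-04).

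Of 16 phosphate genes 0 were higher, 12 lower and 4 did not pass, with a median of -1.34, and 14 were lower adjusted over the list alone (adjusted p = 3.2e-15, but adjusted p = 0.269 with an estimated correlation). PHM6 was 9.85-fold and the phosphate transporter gene PHO89 8.96-fold lower, and PHM8 changed by -1.51 ± 0.15 (SE). PHO3, a related acid phosphatase gene outside the list, was 10.5-fold lower, and the acid phosphatase genes are similar enough in sequence that their probe sets may share signal. PHO84 was uneven in the mutant, with 4.77, 4.71 and 9.08 on the untreated arrays numbered 1, 2 and 3, against 12.13 to 13.25 in wild type.

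Of 23 mating genes 0 were higher, 10 lower and 13 did not pass, with a median of -1.67 (adjusted p = 1.8e-11, but adjusted p = 0.527 with an estimated correlation). FAR1, an inhibitor of the cell cycle in mating, changed by -2.93 ± 0.49, BAR1, which encodes the protease that degrades alpha-factor, by -2.88 ± 0.51, and SST2, a regulator of pheromone signalling, by -2.17 ± 0.28 (SE). The median log2 level of the list was 9.61 and 9.79 on the wild type arrays numbered 1 and 2 but 8.62 on the one numbered 3, and between 7.97 and 8.08 in the mutant. Of 16 markers of alpha cells and sporulating diploids 4 were higher and 1 lower, and 11 did not pass. SGA1, a glucoamylase gene of sporulation, was higher by 1.87 ± 0.22 and NDT80, a meiotic transcription factor gene, by 1.07 ± 0.15 (SE), while SPS4 changed by -1.46 ± 0.37 (SE), a call lost without both mutant arrays numbered 3 (adjusted p = 0.0873).

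Of 49 genes of amino acid synthesis activated by Gcn4, 12 were higher, 0 lower and 37 did not pass, with a median of 0.21 (adjusted p = 1.3e-04, but adjusted p = 0.527 with an estimated correlation). Besides ARG1 and ARG3 these were led by ARG7, also of arginine synthesis, at 1.37 ± 0.17 and the vitamin B6 synthesis gene SNZ1 at 1.99 ± 0.24 (SE). YOR302W, the upstream reading frame of the arginine pathway gene CPA1, was 4.15-fold higher, SEO1, a permease gene, at least 3.94-fold and the wall mannoprotein gene HPF1 4.73-fold. Of 30 glucose-repressed genes 5 were higher and 1 lower, with PCK1 of gluconeogenesis at 1.29 ± 0.17 and the carnitine acetyltransferase genes YAT1 and YAT2 at 1.36 ± 0.21 and 1.04 ± 0.11 (SE; list adjusted p = 0.00545, but adjusted p = 0.706 with an estimated correlation). Of 21 G1/S genes 0 were higher and 5 lower, among them the mating-type endonuclease gene HO at -1.55 ± 0.17 and the cyclin gene PCL2 at -0.83 ± 0.15 (SE; list adjusted p = 9.2e-04, and adjusted p = 0.135 with an estimated correlation).

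Wall genes went both ways. Of 26 mannoprotein genes 3 were higher and 2 lower, with TIR3 at 1.60 ± 0.12 and DAN4 at 1.14 ± 0.22 against CWP1 at -2.16 ± 0.56 (SE). Of the 20 cell wall integrity response genes 3 were lower, with PRM5 at -1.63 ± 0.19 and SRL3 at -0.69 ± 0.17 (SE), and 17 did not pass. Of 27 pathway components 1 was lower, BEM2 at -0.53 ± 0.12 (SE), of 24 glucan genes 1 was lower, CRR1 at -0.92 ± 0.25 (SE), and of 14 chitin genes 1 was higher and 1 lower, both lost without both mutant arrays numbered 3 (GNA1, adjusted p = 0.0961, and CHS1, adjusted p = 0.0685). Of 36 general stress genes 2 were higher and 2 lower, the latter YGP1, a secreted glycoprotein gene, 10.5-fold lower, and the glycerol synthesis gene GPD1 at -0.97 ± 0.19 (SE). Of 20 other SAGA and ADA subunits UBP8, the histone H2B deubiquitinase gene, was lower at -0.76 ± 0.16 and SGF73 was higher at 0.39 ± 0.11 (SE), the latter lost without those arrays (adjusted p = 0.12). Of 26 ergosterol genes 1 was higher and 2 lower, with the squalene synthase gene ERG9 at -1.11 ± 0.13 and ERG25 at 0.71 ± 0.15 (SE). In the cell separation list 1 of 15 was lower, in the respiratory chain list 1 of 37 was higher and 1 lower, and in the unfolded protein response list 1 of 20 was higher. None passed among 55 ribosome biogenesis, 127 ribosomal protein (list adjusted p = 0.0125, median -0.04, and adjusted p = 0.923 with an estimated correlation), 15 glycolysis and 12 seripauperin genes, the last with a median of 0.61 (list adjusted p = 0.0324, and adjusted p = 0.706 with an estimated correlation). None of the 20 iron uptake genes passed either, and their median log2 level was 11.90 on the untreated mutant array numbered 3 against 9.09 and 9.46 on those numbered 1 and 2.

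In all, 525 genes passed between the untreated strains, 262 higher and 263 lower in the mutant, and 115 differed at least 2-fold, 49 higher and 66 lower. With the number of the array as a block 1024 passed, 533 higher and 491 lower, including all 525. That fit counts the treated and untreated arrays of a culture as independent, so the count may be too high. The iron uptake list passed in it (adjusted p = 0.0479, higher, but adjusted p = 0.948 with an estimated correlation and no block). The list's median was higher in the mutant only on the arrays numbered 3, at 11.90 against 10.71. On the mutant arrays numbered 1 and 2 it was lower, at 9.09 and 9.46 against 9.81 on both wild type arrays. With the block the members passing, higher and lower, were 8 and 0 of iron uptake, 4 and 0 of the seripauperins, 10 and 3 of the glucose-repressed genes, and 2 and 5 of general stress. They were 3 and 5 of ergosterol, 2 and 2 of the respiratory chain, 2 and 2 of the unfolded protein response, and 1 and 3 of the glucan genes. They were 1 and 2 of cell separation, 1 and 1 of the pathway components, 2 and 0 of ribosome biogenesis and 0 and 2 of the ribosomal proteins. They were 17 and 3 of the Gcn4 targets, 0 and 14 of the phosphate genes, 0 and 15 of the mating genes, 0 and 7 of the G1/S genes, 5 and 3 of the mannoproteins, 1 and 4 of the integrity response genes, 1 and 2 of the chitin genes and 2 and 1 of the SAGA and ADA subunits. The count was 305 and 301 without the wild type arrays numbered 1 and 2, and 349, 284 and 265 without the mutant arrays numbered 1, 2 and 3. Without single arrays, some of the calls above were lost, with the highest adjusted p as follows: CHS1 0.149, SGF73 0.144, GNA1 0.135, HPF1 0.12, and CRR1 0.113. The same held for SRL3 0.109, SPS4 0.108, CWP1 0.106, BEM2 0.0803, ERG25 0.0612 and FUS1 0.0501, and among the lists for ribosomal proteins 0.315 and seripauperins 0.188. The FUS1 and seripauperin calls were also lost without both mutant arrays numbered 3 (adjusted p = 0.0501 and 0.108).

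**Figure D4:**
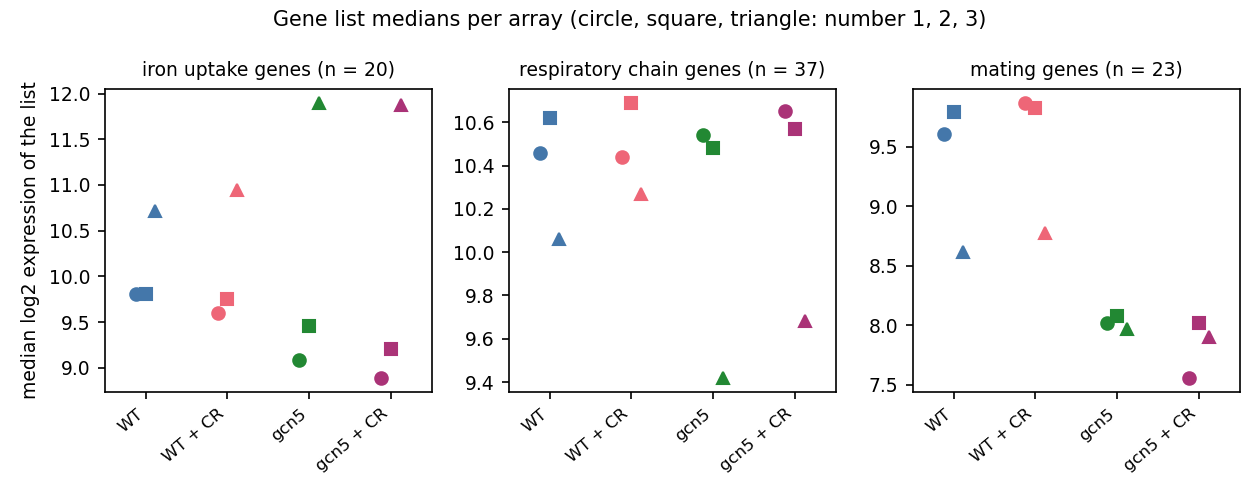
Median log2 level of the iron uptake, respiratory chain and mating lists on each of the 12 arrays. The untreated and Congo Red mutant arrays numbered 3 lie at 11.90 and 11.87 for iron uptake, above the other 10 arrays.

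**Figure D5:**
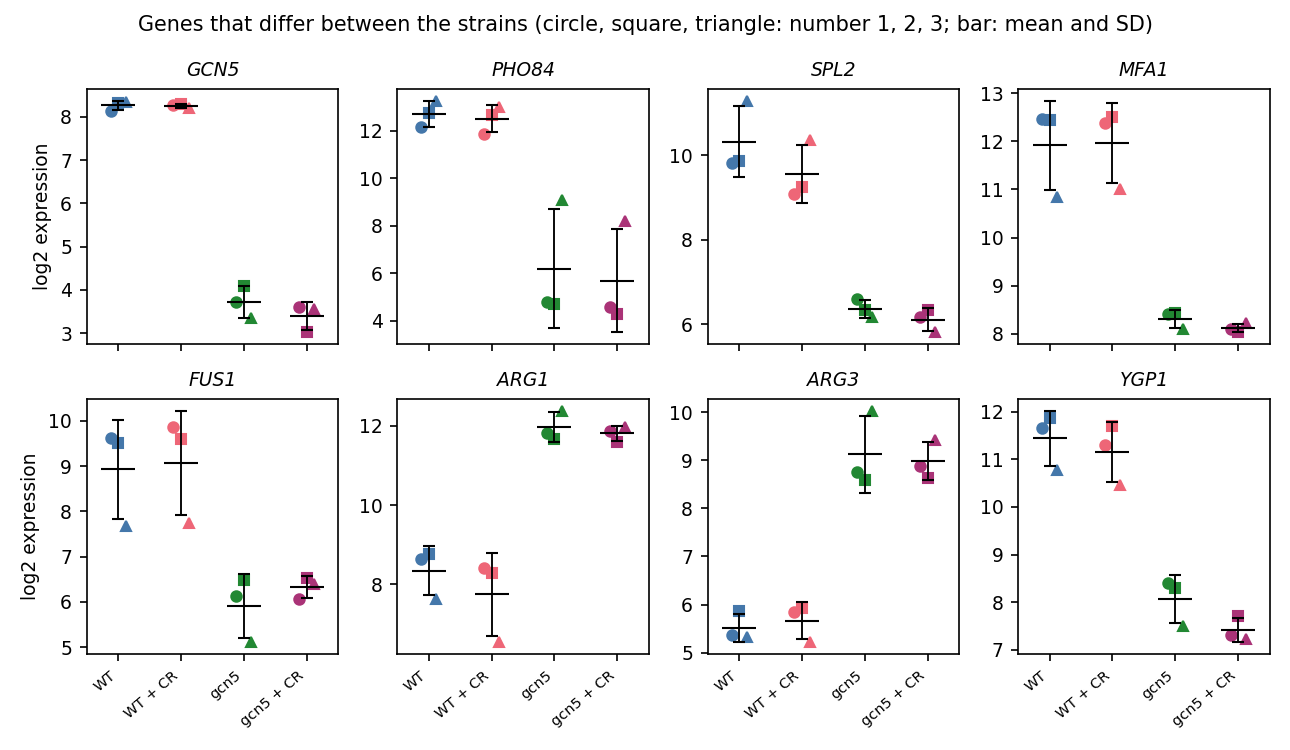
Log2 expression of GCN5 and 7 genes that differ between the strains on each of the 12 arrays, with circles, squares and triangles for the arrays numbered 1, 2 and 3 of a group and horizontal lines with bars for the mean and SD (n = 3). PHO84 lies at 9.08 and 8.19 on the mutant arrays numbered 3 and between 4.28 and 4.77 on the other 4 mutant arrays.

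The fifth comparison set the strains side by side in Congo Red. PHO84 changed by -6.81 ± 1.19 (SE, n = 3 arrays per group; 112-fold lower, adjusted p = 0.00465), AFB1 was 18.8-fold lower (adjusted p = 1.0e-06), PHO89 15.9-fold, YGP1 13.4-fold and FAR1 11.9-fold. ARG1 was higher by 4.06 ± 0.45 and ARG3 by 3.31 ± 0.36 (SE; adjusted p = 4.5e-04 and 3.8e-04), and SNZ1 and TIR3 were 4.04-fold and 3.44-fold higher. Of the cell wall integrity response genes 8 of 20 were lower, 0 were higher and 12 did not pass, with SLT2 at -1.04 ± 0.15 and KDX1 at -1.26 ± 0.22 (SE; list adjusted p = 1.7e-06, but adjusted p = 0.267 with an estimated correlation). BAG7 changed by -1.78 ± 0.12 (SE; adjusted p = 7.4e-06).

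Ribosome biogenesis genes were higher in 14 of 55 cases and lower in 0, with IMP4 at 0.56 ± 0.09 and BRX1 at 0.47 ± 0.08 (SE; list adjusted p = 5.1e-10). Phosphate genes were lower in 12 of 16 cases (adjusted p = 2.3e-12), mating genes in 10 of 23 (adjusted p = 2.0e-10) and chitin genes in 5 of 14, with 1 higher (adjusted p = 0.0196). The chitin genes that were lower included CHS1 at -0.80 ± 0.13 and CHS6 at -0.66 ± 0.11 (SE). Gcn4 targets were higher in 12 of 49 cases and lower in 0 (adjusted p = 3.9e-06). These 5 lists each had an adjusted p = 0.267 with an estimated correlation. General stress genes were lower in 6 of 36 cases, with GPD1 of glycerol synthesis at -1.38 ± 0.19 (SE; list adjusted p = 3.5e-05, and adjusted p = 0.663 with an estimated correlation). Mannoprotein genes were higher in 2 and lower in 6 of 26 cases and glucan genes lower in 3 of 24, and neither list passed. ERG9 changed by -1.46 ± 0.13 and ERO1, which drives disulfide formation, by -0.96 ± 0.24 (SE), the latter lost without both mutant arrays numbered 3 (adjusted p = 0.0657) and without single arrays (adjusted p up to 0.107). Of the remaining lists, pathway components had 1 higher and 4 lower, G1/S genes 0 and 4, glucose-repressed genes 4 and 2, markers of alpha cells and diploids 4 and 1, ergosterol genes 1 and 3, cell separation genes 1 and 2, the unfolded protein response 0 and 2, ribosomal proteins 1 and 0, and the respiratory chain 1 and 0. Without a block, no SAGA and ADA subunit, glycolysis, iron uptake or seripauperin gene passed. With the number as a block, the members of these lists passing, higher and lower, were 2 and 2, 0 and 1, 5 and 0, and 0 and 0 in that order. The median of the iron uptake list was higher in the mutant only on the array numbered 3, at 11.87 against 10.95.

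In Congo Red 586 genes passed, 244 higher and 342 lower in the mutant, and 124 differed at least 2-fold, 32 higher and 92 lower. With the number of the array as a block 1048 passed, 491 higher and 557 lower, including all 586. As between the untreated strains, the count with that block may be too high. The count was 350 and 375 without the wild type arrays numbered 1 and 2, and 316 when only these 6 arrays were fitted, and 11 lists passed without the wild type array numbered 2. The strain effects without and with Congo Red correlated across genes with Pearson's r = 0.84 and Spearman's rho = 0.69. In both conditions 120 genes were higher, against 12 for independent lists, and 184 lower, against 16.8. Treated and untreated parts came from the same divided cultures, so part of that excess may come from the shared cultures.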

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

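Chosen only after the result was seen were the test without both mutant arrays numbered 3 and the counts over other splits of the arrays; the simulation and the comparison of untreated levels were written down before their results were seen. Of the genes, BAG7, YPL088W and HAL1 were singled out because their Congo Red effect differed between the strains by the interaction, with differences of -1.85, -1.56 and -1.46 log2 units, mutant minus wild type. In Congo Red, all 3 mutant arrays lay below all 3 wild type arrays for each of these genes. The interaction that chose them uses the same arrays. Of all 5345 genes, 29% had no overlap between the strains in Congo Red, in either direction. BAG7 was near the floor in both untreated strains, so the size of its difference is uncertain. The interaction called 3 genes, and the other 9 of the 10 splits of the 6 cultures called at most 0. Those splits mix the strains within a group, so strain differences widen the spread and few calls were likely in advance. The 10 splits are also too few for a share under 0.05.

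By the same interaction 8 gene lists were singled out by camera with its preset correlation. The lists with a lower effect in the mutant were the cell wall integrity response (adjusted p = 1.2e-07), its pathway components (adjusted p = 0.0055), chitin synthesis (adjusted p = 0.00266), mannoproteins (adjusted p = 0.0205), general stress (adjusted p = 6.5e-05), glucose-repressed genes (adjusted p = 0.0205) and the unfolded protein response (adjusted p = 0.0147). Ribosome biogenesis fell less in the mutant (adjusted p = 2.8e-20), with median log2 changes of -0.47 in wild type and -0.17 in the mutant. None of the 8 passed with an estimated correlation or with fry. Without the Congo Red mutant array numbered 3, 14 lists passed.

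The pattern behind these calls is a smaller Congo Red rise in the mutant, with a median ratio of 0.493 over the 85 genes at least 2-fold higher in wild type. Simulations argue against the choice of genes on the wild type arrays as its source, since the lowest median ratio in 100 simulations with equal effects was 0.866. Their noise was independent between genes and arrays, so they may understate the spread of the ratio, and they chose a median of 49 genes. Of the 17 genes chosen on the mutant arrays instead, 14 had the larger change in wild type. A single deviating mutant culture does not account for it either, since the ratio was 0.533 without both mutant arrays numbered 3, and the median change per culture was 1.34, 1.23 and 1.37 in wild type and 0.74, 0.69 and 0.52 in the mutant. A higher untreated level in the mutant accounts for little, since the median untreated difference was 0.09 and the median missing rise 0.75. The bootstrap range of the untreated difference was 0.00 to 0.23. It came from resampling the 85 genes, so it does not measure the spread between cultures. A weaker transcriptional response to Congo Red without Gcn5 remains a candidate explanation, as do a different uptake or binding of the dye and a different growth rate of the mutant, which were not tested.

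Probe sets without a gene name were outside the main comparisons. Of 212 above the filter, 25 passed in wild type with Congo Red, 24 higher and 1 lower, and 8 passed in the mutant, 8 higher and 0 lower. That is 11.8% and 3.77%, against 9.24% and 1.16% of named genes.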

How the results depend on the processing

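Leaving out both mutant arrays numbered 3 or all 4 arrays numbered 3 was chosen after seeing the data; all other alternatives were planned. No gene called in the 5 contrasts changed sign under any alternative, and counts stayed within 1.5 times under the filters, the 3 renormalizations, the floor and the mean over probe sets. Leaving out single arrays gave 260 to 428 genes for Congo Red in wild type (72 to 95 at 2-fold), 17 to 56 in the mutant (11 to 20), 3 to 5 for the interaction (3 to 5), 265 to 389 between untreated strains (83 to 127) and 350 to 485 in Congo Red (107 to 147). The induced genes numbered 67 to 89, with 15 to 37 passing in the mutant, 43 to 58 smaller by the interaction over the list alone, a median ratio of 0.467 to 0.529 and a correlation of effects of 0.59 to 0.72. Passing lists numbered 11 to 13, 8 to 11, 6 to 14, 6 to 8 and 7 to 11 in the order of the contrasts. With array weights 785, 150, 16, 1177 and 907 genes passed in that order, 8 at 2-fold for the interaction, and the median ratio was 0.562; the cause was not tested. Fits of only the groups compared, with fewer arrays to estimate the spread, gave 15 genes in the mutant (9 at 2-fold), 15 of the induced genes passing there, and 316 between strains in Congo Red. The replicate block by culture gave 1272 genes in wild type, 212 in the mutant and 30 for the interaction (15 at 2-fold), with 58 of the induced genes chosen in that fit passing in the mutant, because the culture takes up shared spread. The replicate block by number gave 847, 107, 7 (7 at 2-fold), 1024 and 1048. The counts between strains may be too high, because that block treats the treated and untreated arrays of a culture as independent. Every call without a block was also a call with it, and apart from the lists given with the report the block changed no other list call. By deviations from the group means, each of the 12 arrays correlated best with the same-numbered one among the arrays of the strain's other treatment. Across strains, the untreated wild type array numbered 1 reached 0.55 with the mutant Congo Red array numbered 1, against 0.53 with the wild type one. The eBayes fit with trend and robust settings gave 6 genes for the interaction (6 at 2-fold). Without both mutant arrays numbered 3, 39 genes passed in the mutant. Without all 4 arrays numbered 3, 27 genes passed at 2-fold in the mutant, 13 for the interaction (13 at 2-fold), and 14 lists for the interaction; the causes were not tested. An estimated correlation left 3 of 13 lists in wild type, 3 of 9 in the mutant, 0 of 8 for the interaction and 0 of 7 in each strain contrast, and fry 7, 5 and 0 in the first 3. Between the untreated strains fry lost only the ribosomal protein, glucose-repressed and seripauperin calls (adjusted p = 0.296, 0.0591 and 0.179). Between the strains in Congo Red it lost only the general stress call (adjusted p = 0.107). The respiratory chain list in the mutant reversed without the untreated mutant array numbered 3, to a lower effect with adjusted p = 0.15, in a range from 1.4e-09 to 0.758 without single arrays. Over the named genes, passing or not, fits without single arrays lost 253 calls and gained 18. The remaining 3341 results were unchanged, which includes genes that passed in neither fit, so they give no share of calls kept. The other splits of the arrays gave at most 0 genes beside 494 in wild type, 0 beside 62 in the mutant, 0 beside 525 between untreated strains and 1 beside 586 in Congo Red, also among splits that part all same-numbered arrays; only the real split, 1 of 10, reached each count, and 10 splits are too few for a share under 0.05. The other splits mix the groups compared, so real differences widen their spread and low counts were likely in advance. Signal over background was not used here, so the floor at log2 4 is the limit for dim genes.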

Other observations

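Tests on the arrays numbered 3 and on a-specific genes were set up after these patterns were seen, except for the heme and copper lists. The bounds of those lists were written before their values. The requirement that those values clear the bound by more than their spread was added after they were seen. By the bound alone, heme shortage and copper shortage would both have been excluded. The genes named here were chosen after their values were seen.

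Iron uptake genes stood out in the mutant culture numbered 3. All 20 measured Aft1 and Aft2 targets were higher there than the mean of the other mutant cultures in both conditions, with medians of 1.34 log2 units untreated and 1.90 in Congo Red. FIT1, a wall mannoprotein that retains iron carriers, differed by 5.24 and 5.36, the siderophore transporter gene ARN1 by 3.26 and 3.84, the reductase gene FRE5 by 3.59 and 4.77, and TIS11, which degrades mRNAs of iron-using proteins, by 2.74 and 3.14. Of 37 respiratory chain genes 35 were lower in both conditions, with the cytochrome c gene CYC1 at -3.37 and -2.90. In wild type the iron list's median was 10.71 and 10.95 on the arrays numbered 3, against 9.60 to 9.81 on the other 4. The respiratory chain list was also lower on those wild type arrays, with median differences of -0.52 untreated and -0.34 in Congo Red.

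A fault of 1 array does not account for this iron pattern, since both arrays of the culture exceeded the highest of the other 4 mutant arrays by at least 2.41 in the list's median. Copper shortage would also limit iron uptake, and was taken to raise CTR1, FRE7 and CTR3 alike by at least 0.5. Their median difference was -0.11 untreated, below that by more than their spread, and 0.36 in Congo Red. These genes went apart, with CTR1 at 0.48 and 0.52, FRE7 at -0.11 and -0.12, and CTR3 at -0.19 and 0.36. FRE7 was itself lower in the untreated mutant than in untreated wild type, at -2.11 (limma, adjusted p = 0.0059). Its response to copper in the mutant is therefore uncertain, and CTR1 lay near the bound. A median of so few genes cannot exclude copper shortage, which stays open. Heme shortage stays open as well. The smaller median of the 6 genes listed was 0.01, within their spread of the bound of 0.5, and the genes went apart. Untreated, HEM13 lay at -1.14, COX5B at -1.18 and ANB1 at -0.14, but AAC3 at 0.16 and OLE1 at 1.18. ROX1, at 0.59 and 0.10, is activated by heme and would move the other way, and without it the medians were -0.14 and -0.04. Low iron in that culture or its medium, or a mutation in it, may also account for the pattern, and neither was tested.

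A further pattern is the lower level of a-specific genes in the mutant, where 4 of 7 passed between the untreated strains: MFA1 at -3.60, BAR1 at -2.88, STE6 at -1.09 and STE2 at -1.05 (adjusted p = 0.0499), but not MFA2 (adjusted p = 0.19), AGA2 (adjusted p = 0.101) and ASG7 (adjusted p = 0.0919). Alpha cells in the mutant cultures do not account for it, since MF(ALPHA)1, STE3 and SAG1 had a median change of 0.05. A share of cells that are not a cells would lower all 7 genes alike if their probe sets respond alike. The largest and smallest fall differed by 4.76 standard errors of the difference. That pair was picked as the extremes of the 7, which enlarges the value, and the standard error treats the genes as independent. The difference therefore argues only weakly against such a share as the whole source, and a smaller share stays open. Genes switched off in diploids went apart, with HO at -1.55, GPA1 at -1.08 and FUS3 at -0.95 but STE4 at -0.46, STE5 at -0.29, RME1 at -0.23 and STE18 at 0.09, of which the last 4 did not pass. The arrays numbered 3 alone do not carry it, with a median of -2.38 without all 4 of them, against -1.90 with them. A need for Gcn5 at these genes, or an indirect effect such as slower growth, remains a hypothesis that was not tested.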
